A study of Homo sapiens with 11 samples.

How the data were processed

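The data are RNA sequencing libraries of human CD4+ T cells: 2 of uncultured total CD4+ T cells (CD4), and 3 each of DN, Teff and Tr1 cells sorted after 10 days of culture. Total RNA was turned into cDNA with a kit for very small inputs and into libraries by tagmentation, which keeps no record of the strand, so overlapping genes on opposite strands cannot be told apart. Overlap of AC069363.1 with CCL3 was looked up in GENCODE 29. The labels give 2 T cell donors and 2 dendritic cell donors. Culture 1 joins T cell donor 1 and dendritic cell donor 1, culture 2 joins T cell donor 1 and dendritic cell donor 2, and culture 3 joins T cell donor 2 and dendritic cell donor 1. Each culture number gives 1 DN, 1 Teff and 1 Tr1 library, so replicates 1 and 2 share a T cell donor and are not independent people. A culture number stands for a donor pair. Its DN and Tr1 libraries came from the culture named T-allo10 and its Teff library from the culture named T-allo.

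The authors quantified reads with Salmon 1.0.0 and analysed them with limma, and the genome build and annotation release are not given in the sources used here, so no coordinates are printed. The deposited table holds log2 values for 19765 genes and 11 libraries: log2 CPM (counts scaled to a common library size) with an offset of 0.5 counts, scaled to effective library sizes, as the voom function of limma makes them. Its name speaks of counts, but the values include negative numbers, and the lowest value of each library is shared by 257 to 726 genes, as an offset alone gives. Effective library sizes computed from that lowest value were 12423042 to 22953859, and totals computed back from all values 12398051 to 21782020. Linear values sum to 918431 to 1090314 per library. These are estimates of sequenced fragments, not of distinct molecules, and at most 0.779% of the back-computed values under 50 lay within 0.001 of a whole number, so they were not treated as counts. Every gene had at least 10 back-computed counts in at least 2 libraries, so genes with low values had been removed before deposit, and no further filter was used. Of the genes, 590 have no symbol. Symbols and identifiers are those of the deposited table, and no value column was left without a sample.

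The design fixed before the data were examined called for limma with a mean-variance trend where a table holds log2 values, and this was run with limma 3.58.1 in R 4.3.3 on the values as deposited. Tr1 against all other libraries was fitted as 2 groups of 3 and 8 libraries. Differences between CD4, DN and Teff cells therefore count as spread within the 8. The contrasts Tr1 against DN, Tr1 against Teff, Tr1 against CD4 and DN against Teff came from 1 fit of the 4 groups with 7 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no block for donor or culture. Blocks for T cell donor and, among the 9 cultured libraries, for culture were alternatives, and their counts are given with the comparisons. A check of the pairing subtracted group means and correlated the residuals of 9882 genes across libraries. Pairs with 1 culture number gave 0.198 to 0.475 and the highest other correlation was -0.00701, so the culture numbers pair the samples. Genes higher or lower in Tr1 than in each of the 3 other groups were those called in 1 direction in all 3 contrasts.

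Most named genes followed a rule written before the data were examined. CD4, CD86, FOXP3 and LYZ, the 16 genes drawn in a figure, and the lysosomal genes, PTMS, MERTK, HMOX1 and LYN of the closing part were chosen outside it, after their values were seen. For each comparison the rule gives ITGA2 and LAG3, the 8 largest rises and the 8 largest falls among called genes, and up to 6 members with the smallest p from each list described. The rises and falls also had to lie in the upper part of expression, at or above the median gene in the group with the higher level, with no overlap between the values of both groups. That part of the rule leaves out XIST, Y-linked genes, T cell receptor and immunoglobulin segments, HLA genes and features with no symbol. For a fold, libraries under 3 counts in the group with the lower level were set to 3 counts, taken at the smallest library of that group, and the fold is then given as a lower bound.

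A set of 29 gene lists was fixed before the data were examined: sort markers, co-inhibitory receptors, co-stimulatory receptors and ligands, Tr1-associated genes, FOXP3 regulatory T cell genes, cytokines, chemokines, chemokine and homing receptors, integrins, cytotoxic granule genes, naive and central memory T cell genes, helper lineage transcription factors, exhaustion-associated genes, immediate early and T cell receptor response genes, cell cycle genes, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, type I interferon response, MHC class II genes and unfolded protein response. The others serve as checks: markers of myeloid and dendritic cells, B cells, natural killer cells, CD8 and gamma-delta T cells, platelets and erythroid cells, CD4 T cell identity genes, mitochondrially encoded transcripts and heat shock genes. Lists share some members. Each was tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 29 lists of a comparison, and again with an estimated correlation and with fry.

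The fit was tested on simulated data with the gene means, library sizes and within-group spread of these libraries. Each comparison had 200 changed genes, and all other gene means were equal in the 4 groups. The fit recovered 31% of changes of log2 1 and 59% of changes of log2 2 for Tr1 against all others, 11% and 47% against DN, 13% and 44% against Teff, 10% and 44% against CD4, and 23% and 51% for DN against Teff. Real differences between CD4, DN and Teff count as spread in the 2-group fit but were absent here. Recovery for Tr1 against all others is therefore overstated, and its values cannot be ranked against those of the other comparisons. At most 5.26% of the genes called in the simulated data were false, and 0 genes were called when none was changed. The simulated libraries held no correlation within a culture number, so these values do not cover the pairing of the real libraries. Smaller changes are therefore often missed at this number of libraries.

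Alternatives were quantile normalization, the upper part of mean expression alone, limma without the trend, blocks for T cell donor and culture, the mean of both cultures of T cell donor 1, the libraries of the groups compared alone, Tr1 against the mean of the group means, Tr1 against DN and Teff alone, and leaving out each library in turn. Chosen after seeing the data were limma with voom weights, the fit without the 3 cultured libraries with the most LYZ, some of the alternatives for the genes shared by the 3 contrasts, and a list of 53 lysosomal genes. Alternatives that need counts were not run, since the deposited values are log2 and not counts, and the alternative without a filter equals the values as deposited.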

Results

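Gene expression was measured by RNA sequencing in 11 libraries of human CD4+ T cells that fall into 4 groups. The CD4 group holds 2 libraries of total CD4+ T cells that had not been cultured, 1 from each of 2 T cell donors. The other groups hold 3 libraries each, of memory CD4+ T cells sorted by flow cytometry after 10 days of culture with dendritic cells of another donor. Tr1 cells (type 1 regulatory T cells) carried both CD49b, an integrin chain encoded by ITGA2, and LAG3, an inhibitory receptor, and came from the culture named T-allo10. DN cells carried neither marker and came from the same T-allo10 cultures. Teff cells carried neither marker and came from the culture named T-allo. Replicates 1 and 2 of each cultured group share T cell donor 1 and differ in the dendritic cell donor, while replicate 3 comes from T cell donor 2. The 3 cultures thus stand for 2 T cell donors.

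Total counts computed back from the deposited values were 12398051 and 17941986 for CD4 replicates 1 and 2. They were 16025164, 15544557 and 15127160 for DN, 21782020, 14295246 and 21188584 for Teff, and 20075812, 17700738 and 17802061 for Tr1. A count of 0 allows a level of up to 0.131 to 0.241 CPM (counts scaled to a common library size) depending on the library, for counting error only. Levels are given as log2 CPM, mean ± SD over the libraries of a group, and a log2 difference of 1 is a 2-fold change. A fold given as at least a value has libraries under 3 counts in the group with the lower level set to 3 counts, and where that group held 3 counts or fewer in all, levels are given in its place. Apart from calls made with culture as a block, no gene given below as higher or lower in a comparison had overlapping values in the groups compared. CD4, CD86, FOXP3 and LYZ were named, and the 16 genes drawn in a figure picked, after their values were seen, and the other genes were named by a rule set before.

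The CD4 and the Tr1 libraries lay apart from the DN and Teff libraries. Principal component 1 held 54.8% of the variance and put the CD4 libraries at scores of -79.3 and -81.9 and the Tr1 libraries at 36.2 to 56.8. Component 2 held 18.3% and separated the Tr1 libraries, at 25.1 to 38.1, from the DN and Teff libraries, at -28.0 to -15.9. Across genes, which are not independent replicates, Spearman's rho between pairs of Tr1 libraries was 0.947 to 0.959. It was 0.923 to 0.944 between Tr1 and Teff, 0.901 to 0.923 between Tr1 and DN and 0.849 to 0.873 between Tr1 and CD4 libraries. Between DN and Teff it was 0.928 to 0.948, which overlaps the 0.941 to 0.953 between pairs of DN libraries. Markers of myeloid cells were not evenly spread. The sum of 10 abundant ones, LYZ among them, was 693 and 1034 CPM in the CD4 libraries and 12.1, 9.88 and 64.2 CPM in DN replicates 1, 2 and 3. It was 7.56, 6.89 and 56.8 CPM in Teff and 110.4, 16.6 and 15.6 CPM in Tr1 replicates 1, 2 and 3.

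**Figure D1:**
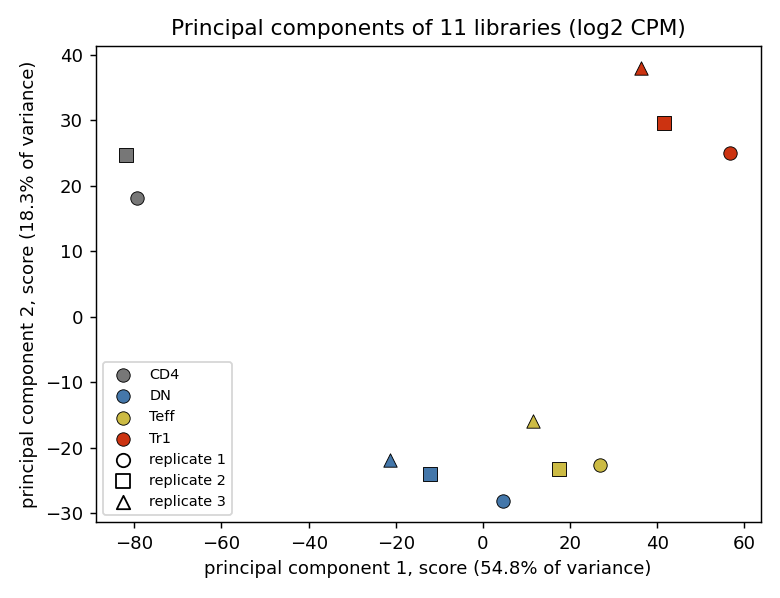
Scores of the 11 libraries on principal components 1 (horizontal axis) and 2 (vertical axis) of the log2 CPM values, which hold 54.8% and 18.3% of the variance. Each point is a library, colours mark the 4 groups and symbols the replicate, and the Tr1 libraries lie between 36.2 and 56.8 on component 1 and between 25.1 and 38.1 on component 2.

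The comparison of Tr1 cells with all other cells is the one the series names as its design, and asks what sets the sorted CD49b+LAG3+ cells apart. LAG3, an inhibitory receptor that binds MHC class II molecules, was 94.7-fold higher in Tr1 cells (12.69 ± 0.17 against 6.13 ± 2.16 log2 CPM, n = 3 and 8). ITGA2 was 13.0-fold higher (4.81 ± 0.47 against 1.11 ± 1.30 log2 CPM), and both genes encode the proteins the cells were sorted on. IL10, the gene of the suppressive cytokine interleukin 10, was at least 101-fold higher (6.88 ± 0.51 against 0.17 ± 1.63 log2 CPM, adjusted p = 0.000451). CTLA4 and PDCD1, which encode inhibitory receptors of T cells, were 11.6-fold and 8.53-fold higher. CCR7, the receptor that guides T cells to lymph nodes, was 9.70-fold lower (5.17 ± 1.06 against 8.45 ± 0.31 log2 CPM, adjusted p = 0.000119).

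Of 19765 genes tested with limma, 1686 differed, 891 higher and 795 lower in Tr1 cells, and 704 and 662 of these by at least 2-fold. Besides LAG3 and IL10, the named rises held CSF2, which encodes the growth factor GM-CSF (at least 53.3-fold), FAXC (at least 47.3-fold) and the noncoding gene RP11-305L7.3 (at least 40.7-fold). AC069363.1 was at least 37.9-fold higher. GENCODE 29 places its identifier over CCL3 on the opposite strand, so its reads may be those of CCL3. The named falls held ADAM23, a membrane protein of the disintegrin family (at least 120.2-fold, adjusted p = 4.03e-05), PLAC8 (47.2-fold) and the noncoding gene LINC00402 (at least 20.8-fold). The ubiquitin ligase gene RNF144A (22.9-fold), SPON1 (22.6-fold) and VIPR1, a receptor of vasoactive intestinal peptide (22.2-fold), fell too. FAIM2, CCL4L2, ANKRD18A and KRT1 were also among the 8 largest rises or falls, but lost the call when 1 Tr1 library was left out. FAIM2 then had an adjusted p of 0.0591 without Tr1 replicate 1, 0.0568 without Tr1 replicate 2 and 0.0530 without Tr1 replicate 3. KRT1 had 0.0919 without Tr1 replicate 1, 0.0861 without Tr1 replicate 2 and 0.0670 without Tr1 replicate 3. ANKRD18A had 0.0797 without Tr1 replicate 1 and 0.0556 without Tr1 replicate 3, and CCL4L2, which has near-identical copies, had 0.0529 without Tr1 replicate 1.

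Co-stimulatory genes held 12 higher and 0 lower members of 21 measured, or 15 and 0 adjusted over the list alone. TNFRSF1B (10.2-fold), TNFRSF18 (10.6-fold), TNFRSF4 (7.86-fold) and ICOS (2.95-fold) were among the higher ones. Co-stimulatory genes had a camera adjusted p = 6.16e-11 as a list, higher, and adjusted p = 0.0116 with an estimated correlation. Among co-inhibitory receptors, 7 of 18 measured were higher and 0 lower (9 and 0 adjusted over the list alone). For co-inhibitory receptors, camera gave adjusted p = 0.000113 (higher), and adjusted p = 0.116 with an estimated correlation. The Tr1-associated list holds IL10 but neither sort marker. Of 18 Tr1-associated genes measured, 7 were higher and 0 lower, and 11 and 0 adjusted over the list alone. The transcription factor genes PRDM1 (5.85-fold) and MAF (6.06-fold) rose. As a list, Tr1-associated genes were higher (camera adjusted p = 1.55e-07, and adjusted p = 0.0414 with an estimated correlation). Exhaustion-associated genes held 10 higher and 0 lower members of 17 measured, or 13 and 0 adjusted over the list alone. TOX (4.94-fold) and TOX2 (7.86-fold), which encode nuclear factors of chronically stimulated T cells, rose. Exhaustion-associated genes had a camera adjusted p = 2.16e-11 as a list, higher, and adjusted p = 0.0122 with an estimated correlation. Among cytotoxic granule genes, 6 of 16 measured were higher and 0 lower (6 and 0 adjusted over the list alone). The granzyme genes GZMB (11.6-fold) and GZMA (10.8-fold) and NKG7 (6.09-fold) rose. For cytotoxic granule genes, camera gave adjusted p = 5.26e-08 (higher), and adjusted p = 0.0116 with an estimated correlation. Of 6 CD8 and gamma-delta T cell markers measured, 1 were higher and 0 lower, and 2 and 0 adjusted over the list alone. CD8A was 3.30-fold higher (3.99 ± 0.59 against 2.27 ± 0.39 log2 CPM). As a list, CD8 and gamma-delta T cell markers were higher (camera adjusted p = 0.0113, and adjusted p = 0.265 with an estimated correlation).

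Cytokines held 6 higher and 2 lower members of 21 measured, or 8 and 2 adjusted over the list alone. IL21 (at least 38.1-fold), IL4 (at least 21.3-fold), CSF1 (10.3-fold) and IFNG, the gene of interferon gamma (8.87-fold), were higher. Cytokines had a camera adjusted p = 0.000379 as a list, higher, and adjusted p = 0.0902 with an estimated correlation. Among chemokines, 2 of 11 measured were higher and 0 lower (4 and 0 adjusted over the list alone). CCL4 was 20.3-fold higher. For chemokines, camera gave adjusted p = 0.00227 (higher), and adjusted p = 0.0864 with an estimated correlation. Of 19 naive and central memory genes measured, 1 were higher and 7 lower, and 1 and 8 adjusted over the list alone. Besides CCR7, TCF7 (7.49-fold), LEF1 (6.38-fold) and IL7R (3.54-fold) fell. As a list, naive and central memory genes were lower (camera adjusted p = 0.00344, and adjusted p = 0.265 with an estimated correlation). Cell cycle genes held 2 higher and 0 lower members of 34 measured, or 3 and 0 adjusted over the list alone. Cell cycle genes had a camera adjusted p = 2.88e-09 as a list, higher, but did not pass with an estimated correlation (adjusted p = 0.331) or with fry (adjusted p = 0.0839). Among glycolysis genes, 5 of 21 measured were higher and 1 lower (11 and 1 adjusted over the list alone). PKM (2.63-fold) and PGAM1 (3.6-fold) rose and ENO2 fell (2.19-fold). For glycolysis genes, camera gave adjusted p = 8.32e-06 (higher), and adjusted p = 0.116 with an estimated correlation. Of 22 chemokine and homing receptors measured, 4 were higher and 5 lower, and 6 and 8 adjusted over the list alone. Chemokine and homing receptors did not pass as a list with camera (adjusted p = 0.579). Integrins held 4 higher and 1 lower members of 13 measured, or 4 and 2 adjusted over the list alone. ITGB1 (2.44-fold) and ITGB2 (2.73-fold) were higher. As a list, integrins did not pass with camera (adjusted p = 0.0803). CD4 was 10.6-fold higher in Tr1 cells (11.96 ± 0.10 against 8.56 ± 0.85 log2 CPM), but it lies next to LAG3, and reads running on from LAG3 and a rise of CD4 itself cannot be told apart. FOXP3, the lineage factor of another kind of regulatory T cell, passed the test in none of the 5 comparisons, nor with culture as a block (adjusted p = 0.331 against DN, 0.472 against Teff and 0.933 for DN against Teff). Its level was 4.24 ± 0.74 log2 CPM in Tr1, 4.70 ± 0.63 in DN, 4.63 ± 0.91 in Teff and 3.42 ± 0.19 in CD4.

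The count of 1686 was 1625 with T cell donor as a block, 301 when the cultures of T cell donor 1 were averaged and the donor was a block, 5147 in a 4-group fit of Tr1 against the mean of the 3 group means, and 649, 685 and 731 without Tr1 replicate 1, 2 and 3. Without Tr1 replicate 1, DN replicate 3 and Teff replicate 3, which held the most LYZ among the cultured libraries, it was 300. DN and Teff then come from T cell donor 1 alone while Tr1 keeps both donors. The fall therefore cannot be tied to myeloid RNA. More genes were lower than higher under quantile normalization (823 and 689), without a mean-variance trend (699 and 623) and without Tr1 replicate 3 (379 and 352).

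**Figure D2:**
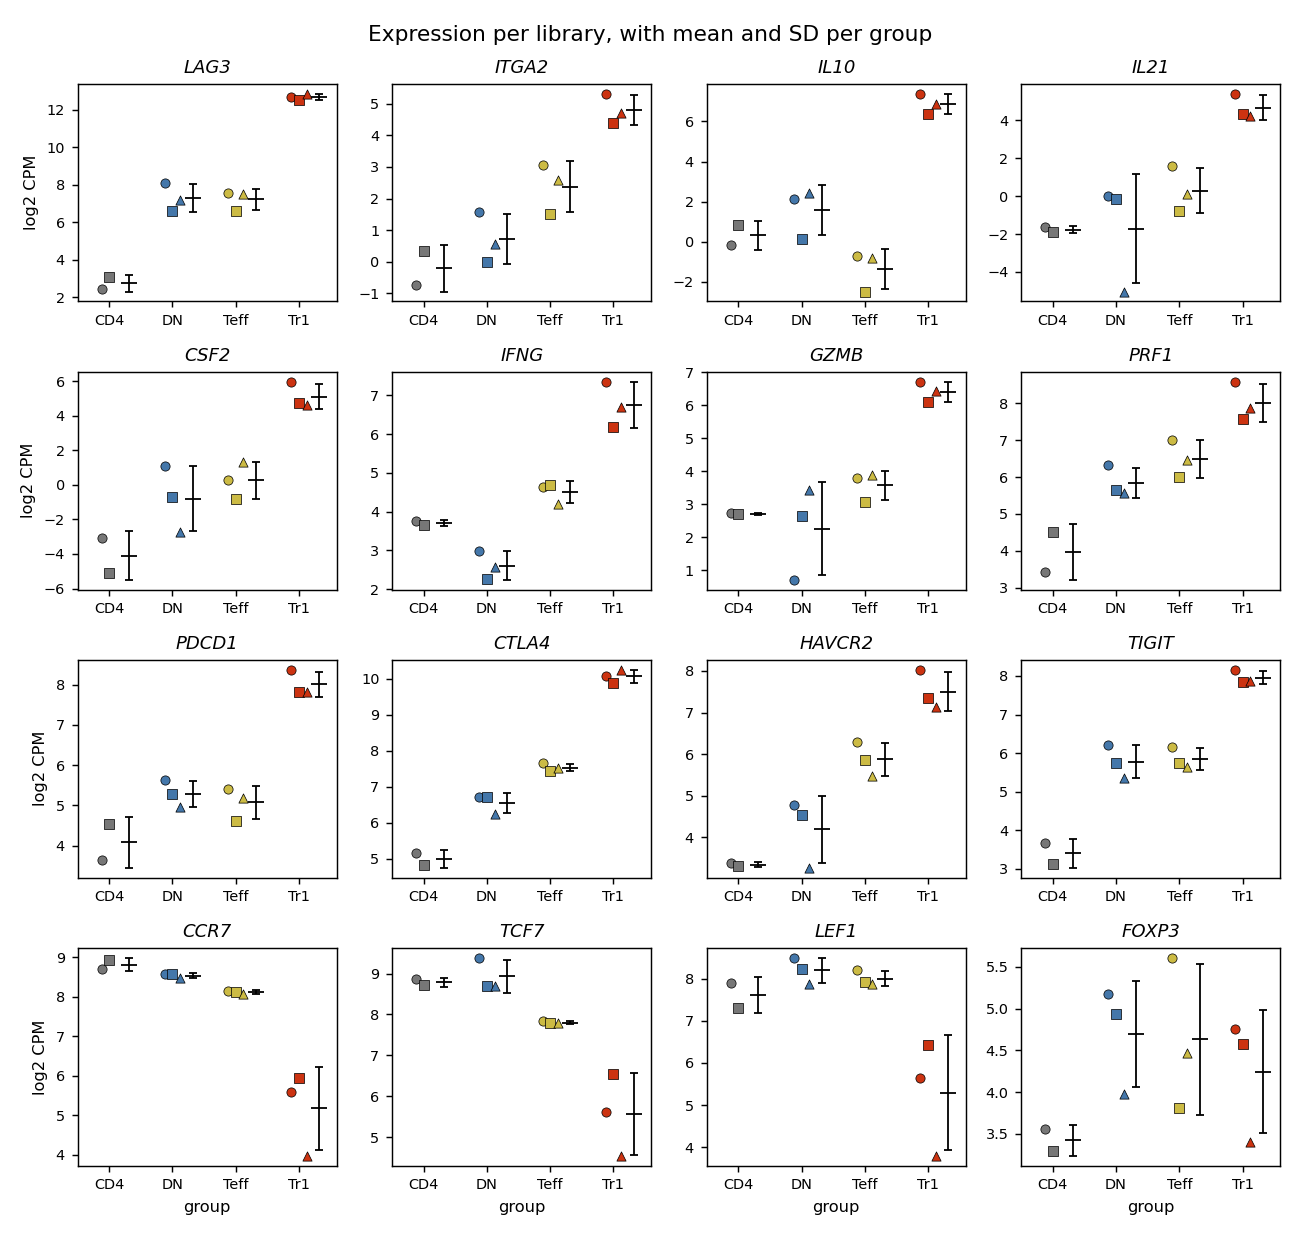
Expression of 16 genes in log2 CPM (vertical axis) by group (horizontal axis), where each symbol is a library, its shape gives the replicate, and the bar beside each group is the mean with its SD (n = 2 for CD4, 3 for the others). LAG3 lies at 12.69 ± 0.17 in Tr1 and at 7.30 ± 0.75 in DN, and CCR7, TCF7 and LEF1 are lower in Tr1 than in the other groups.

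Tr1 and DN cells were sorted from the same T-allo10 cultures, so this comparison asks how the cells with both markers differ from those with neither. LAG3 was 42.1-fold higher in Tr1 cells (12.69 ± 0.17 against 7.30 ± 0.75 log2 CPM, n = 3 each), ITGA2 17.1-fold (4.81 ± 0.47 against 0.71 ± 0.79 log2 CPM) and IL10 39.5-fold (6.88 ± 0.51 against 1.58 ± 1.26 log2 CPM, adjusted p = 9.23e-05). IFNG was 17.6-fold higher and GZMB, a protease of cytotoxic granules, 17.7-fold higher. MKI67, the gene of the proliferation marker Ki-67, was 7.30-fold higher (5.83 ± 0.40 against 2.96 ± 1.60 log2 CPM). ADAM23 was at least 285-fold lower in Tr1 cells (-3.67 ± 1.35 against 5.71 ± 0.29 log2 CPM, adjusted p = 5.43e-07), and CCR7 10.3-fold lower.

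With limma, 3532 genes differed, 2026 higher and 1506 lower in Tr1 cells, and 1255 and 1082 of these by at least 2-fold. The named rises held IL21, a cytokine of helper T cells (at least 45.2-fold), CSF2 (at least 55.7-fold), the Ras activator gene RASGRP4 (at least 38-fold) and FAXC (at least 93.3-fold). AC069363.1 (at least 39.2-fold), where reads of CCL3 may count, and CCL4L2, which has near-identical copies (at least 61.2-fold), were higher. The gene ENSG00000235641.5, whose symbol, LINC00484, the table also gives to another identifier, was at least 41.5-fold higher. RP11-529K1.3 was at a count of 0 in every DN library and at least 40-fold higher, taking 3 counts per library as the floor. Besides ADAM23, the named falls were ANKRD18A (at least 137-fold), the keratin gene KRT1 (104-fold), PLAC8 (62.9-fold) and LINC00402 (at least 30.4-fold). SPON1 (55.2-fold), FLJ21408 (47.2-fold) and HPCAL4, a neuronal calcium sensor (at least 24.8-fold), were the others.

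Among co-inhibitory receptors, 6 of 18 measured were higher and 0 lower (6 and 0 adjusted over the list alone). CTLA4 (11.4-fold), PDCD1 (6.55-fold), HAVCR2, which encodes TIM-3 (9.95-fold), and TIGIT (4.54-fold) rose. For co-inhibitory receptors, camera gave adjusted p = 0.000235 (higher), and adjusted p = 0.151 with an estimated correlation. Of 21 co-stimulatory genes measured, 15 were higher and 1 lower, and 15 and 1 adjusted over the list alone. TNFRSF4 (8.93-fold) and TNFRSF1B (9.63-fold) were among the higher ones. As a list, co-stimulatory genes were higher (camera adjusted p = 1.48e-09, and adjusted p = 0.0469 with an estimated correlation). Tr1-associated genes held 11 higher and 0 lower members of 18 measured, or 11 and 0 adjusted over the list alone. PRDM1 (6.81-fold), IRF4 (7.87-fold), MAF (4.64-fold) and ENTPD1, which encodes the ectoenzyme CD39 (11-fold), rose. Tr1-associated genes had a camera adjusted p = 1.45e-08 as a list, higher, and adjusted p = 0.0469 with an estimated correlation. Among exhaustion-associated genes, 13 of 17 measured were higher and 0 lower (14 and 0 adjusted over the list alone). For exhaustion-associated genes, camera gave adjusted p = 8.20e-16 (higher), and adjusted p = 0.0249 with an estimated correlation. Of 16 cytotoxic granule genes measured, 7 were higher and 0 lower, and 8 and 0 adjusted over the list alone. GNLY (13.7-fold), GZMA (10.2-fold) and NKG7 (6.40-fold) rose beside GZMB. As a list, cytotoxic granule genes were higher (camera adjusted p = 3.48e-08, and adjusted p = 0.0469 with an estimated correlation). CD8 and gamma-delta T cell markers held 1 higher and 0 lower members of 6 measured, or 1 and 0 adjusted over the list alone. CD8A was 3.04-fold higher (3.99 ± 0.59 against 2.39 ± 0.47 log2 CPM). As a list, CD8 and gamma-delta T cell markers did not pass with camera (adjusted p = 0.163), though with fry they were higher (adjusted p = 0.0464). Among FOXP3 regulatory T cell genes, 6 of 15 measured were higher and 1 lower (6 and 1 adjusted over the list alone). The higher ones included CTLA4 and TIGIT, which other activated T cells express too. For FOXP3 regulatory T cell genes, camera gave adjusted p = 0.000539 (higher), and adjusted p = 0.264 with an estimated correlation.

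Of 21 cytokines measured, 9 were higher and 3 lower, and 10 and 3 adjusted over the list alone. As a list, cytokines were higher (camera adjusted p = 4.62e-05, and adjusted p = 0.151 with an estimated correlation). Chemokines held 3 higher and 0 lower members of 11 measured, or 3 and 0 adjusted over the list alone. CCL3 (32.7-fold) and CCL4 (34.5-fold) were higher. Chemokines had a camera adjusted p = 0.00626 as a list, higher, and adjusted p = 0.243 with an estimated correlation. Among chemokine and homing receptors, 6 of 22 measured were higher and 6 lower (7 and 8 adjusted over the list alone). CXCR6 (10.8-fold) and CCR2 (15.1-fold), receptors for inflammatory chemokines, rose, while S1PR1, which directs T cells out of lymph nodes, fell (4.46-fold). As a list, chemokine and homing receptors did not pass with camera (adjusted p = 0.972). Of 19 naive and central memory genes measured, 1 were higher and 8 lower, and 1 and 10 adjusted over the list alone. TCF7 (10.3-fold), LEF1 (7.44-fold) and IL7R (4.99-fold) fell. As a list, naive and central memory genes were lower (camera adjusted p = 0.000251, and adjusted p = 0.157 with an estimated correlation). Cell cycle genes held 25 higher and 0 lower members of 34 measured, or 30 and 0 adjusted over the list alone. TPX2 (7.36-fold) and BUB1B (8.29-fold), which act in mitosis, rose. Cell cycle genes had a camera adjusted p = 1.13e-14 as a list, higher, and adjusted p = 0.151 with an estimated correlation.

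Among glycolysis genes, 11 of 21 measured were higher and 1 lower (11 and 1 adjusted over the list alone). For glycolysis genes, camera gave adjusted p = 1.93e-05 (higher), and adjusted p = 0.157 with an estimated correlation. Of 30 oxidative phosphorylation genes measured, 7 were higher and 0 lower, and 8 and 0 adjusted over the list alone. As a list, oxidative phosphorylation genes were higher (camera adjusted p = 0.000120, and adjusted p = 0.334 with an estimated correlation). MHC class II genes held 6 higher and 0 lower members of 13 measured, or 6 and 0 adjusted over the list alone. HLA-DRA (2.72-fold), HLA-DMA (2.58-fold) and CD74, the invariant chain (1.88-fold), were higher. MHC class II genes had a camera adjusted p = 0.000333 as a list, higher, and adjusted p = 0.151 with an estimated correlation. CD86, a ligand of CTLA4 made by antigen-presenting cells and some activated T cells, was 31.1-fold higher (4.30 ± 0.60 against -0.66 ± 0.94 log2 CPM). Beside it, the median of the myeloid and dendritic cell markers was 0.62 ± 1.09 log2 CPM in Tr1 and -0.10 ± 0.91 in DN cells.

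With culture as a block among the 9 cultured libraries, 5026 genes differed (2929 higher and 2097 lower), and with T cell donor as a block 4014 did. The count of 3532 was 2349 without DN replicate 3 and 1511 without the 3 cultured libraries with the most LYZ, and under quantile normalization more genes were lower (1654) than higher (1568).

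Against Teff cells, which carried neither sort marker and grew in the T-allo culture, the sorted population and the kind of culture differ at once. IL10 was at least 287-fold higher in Tr1 cells (6.88 ± 0.51 against -1.35 ± 0.99 log2 CPM, n = 3 each, adjusted p = 1.00e-05). LAG3 was 44.6-fold higher (12.69 ± 0.17 against 7.22 ± 0.55 log2 CPM) and ITGA2 5.39-fold (4.81 ± 0.47 against 2.38 ± 0.80 log2 CPM). CSF2 was 28.9-fold higher and IFNG 4.70-fold. ADAM23 was at least 90.8-fold lower and CCR7 7.70-fold lower.

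With limma, 1801 genes differed, 1051 higher and 750 lower in Tr1 cells, and 718 and 486 of these by at least 2-fold. Besides IL10, the named rises held FAIM2, an inhibitor of FAS-induced cell death (at least 134-fold), and CD276, which encodes the immune checkpoint protein B7-H3 (at least 75.6-fold). The serine protease gene HTRA1 (at least 47.0-fold), FAXC (at least 43.2-fold), PTGIS, the prostacyclin synthase (at least 56.1-fold), and CCL4L2 (at least 55.9-fold) rose too. PHEX was at least 45.3-fold higher, but its call ended, with an adjusted p of 0.0524 without Tr1 replicate 1 and 0.0602 without Tr1 replicate 2. Besides ADAM23, the named falls held the collagen gene COL6A1 (at least 28.8-fold) and CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor (43.1-fold). GPR15, a receptor that homes T cells to the gut (26.3-fold), LINC00402 (at least 20.2-fold), PLAC8 (26.7-fold), RNF144A (26-fold) and VIPR1 (15.0-fold) were the others.

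Among exhaustion-associated genes, 13 of 17 measured were higher and 0 lower (14 and 0 adjusted over the list alone). TOX2 (5.42-fold) and PDCD1 (7.58-fold) rose. For exhaustion-associated genes, camera gave adjusted p = 5.45e-16 (higher), and adjusted p = 0.0240 with an estimated correlation. Of 21 co-stimulatory genes measured, 14 were higher and 1 lower, and 16 and 1 adjusted over the list alone. TNFSF9, the ligand of 4-1BB (25.6-fold), and TNFRSF1B (9.91-fold) rose. As a list, co-stimulatory genes were higher (camera adjusted p = 7.24e-13, and adjusted p = 0.0403 with an estimated correlation). Co-inhibitory receptors held 5 higher and 1 lower members of 18 measured, or 9 and 2 adjusted over the list alone. CTLA4 (5.78-fold) and TIGIT (4.33-fold) were among the higher ones. Co-inhibitory receptors had a camera adjusted p = 0.000163 as a list, higher, and adjusted p = 0.109 with an estimated correlation. Among Tr1-associated genes, 9 of 18 measured were higher and 0 lower (10 and 0 adjusted over the list alone). PRDM1 (4.44-fold) and MAF (5.08-fold) rose. For Tr1-associated genes, camera gave adjusted p = 6.33e-08 (higher), and adjusted p = 0.0441 with an estimated correlation. Of 16 cytotoxic granule genes measured, 8 were higher and 0 lower, and 8 and 0 adjusted over the list alone. GZMB (7.14-fold) and GZMA (6.34-fold) rose. As a list, cytotoxic granule genes were higher (camera adjusted p = 6.33e-08, and adjusted p = 0.0441 with an estimated correlation). CD8 and gamma-delta T cell markers held 1 higher and 0 lower members of 6 measured, or 1 and 0 adjusted over the list alone. CD8A was 3.27-fold higher (3.99 ± 0.59 against 2.29 ± 0.29 log2 CPM). CD8 and gamma-delta T cell markers did not pass as a list with camera (adjusted p = 0.0868), though with fry they were higher (adjusted p = 0.0430). Among FOXP3 regulatory T cell genes, 6 of 15 measured were higher and 2 lower (6 and 2 adjusted over the list alone). For FOXP3 regulatory T cell genes, camera gave adjusted p = 0.0111 (higher), and adjusted p = 0.373 with an estimated correlation. This list's median log2 difference of -0.14 was opposite in sign to its mean of 0.60 and to its test. LRRC32, which anchors latent TGF-beta at the cell surface, was 17.0-fold higher.

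Of 21 cytokines measured, 9 were higher and 2 lower, and 10 and 3 adjusted over the list alone. CSF1 (8.79-fold) and TNF (2.62-fold) were higher. As a list, cytokines were higher (camera adjusted p = 0.000128, and adjusted p = 0.129 with an estimated correlation). Chemokines held 4 higher and 0 lower members of 11 measured, or 5 and 0 adjusted over the list alone. CCL3 (11.5-fold), CCL4 (10.8-fold) and CCL18, a chemokine of myeloid cells (2.55 ± 1.71 against -4.38 ± 1.41 log2 CPM), were higher. Chemokines had a camera adjusted p = 0.000494 as a list, higher, and adjusted p = 0.129 with an estimated correlation. Among immediate early genes, 9 of 20 measured were higher and 1 lower (11 and 1 adjusted over the list alone). NR4A2 (5.41-fold) and JUNB (2.56-fold) rose and MYC fell (3.87-fold). For immediate early genes, camera gave adjusted p = 7.42e-05 (higher), and adjusted p = 0.109 with an estimated correlation. Of 31 type I interferon genes measured, 11 were higher and 2 lower, and 13 and 2 adjusted over the list alone. IFI44L (4.69-fold) and MX1 (3.12-fold) rose and IFIT2 fell (4.99-fold). As a list, type I interferon genes were higher (camera adjusted p = 4.42e-06, and adjusted p = 0.0661 with an estimated correlation). Glycolysis genes held 8 higher and 1 lower members of 21 measured, or 14 and 1 adjusted over the list alone. Glycolysis genes had a camera adjusted p = 2.86e-07 as a list, higher, and adjusted p = 0.112 with an estimated correlation.

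Among MHC class II genes, 0 of 13 measured were higher and 4 lower (0 and 4 adjusted over the list alone). CIITA, the master regulator of these genes, was 3.52-fold lower. For MHC class II genes, camera gave adjusted p = 0.000494 (lower), and adjusted p = 0.129 with an estimated correlation. Of 34 cell cycle genes measured, 0 were higher and 0 lower, and 0 and 0 adjusted over the list alone. As a list, cell cycle genes passed as higher only with camera at the preset correlation (adjusted p = 0.0361). They did not pass with an estimated correlation (adjusted p = 0.631) or with fry (adjusted p = 0.489). At an unadjusted p under 0.05 in limma, 3 cell cycle genes differed, and the median log2 difference of all 34 measured was 0.34. With culture as a block, TPX2, BUB1B and CENPE were higher (adjusted p = 0.0203, 0.0318 and 0.0470). Naive and central memory genes held 3 higher and 6 lower members of 19 measured, or 5 and 8 adjusted over the list alone. TCF7 (4.70-fold) and IL7R (3.35-fold) fell and BCL2 rose (3.09-fold). As a list, naive and central memory genes did not pass with camera (adjusted p = 0.255). Among myeloid and dendritic cell markers, 4 of 28 measured were higher and 1 lower (6 and 1 adjusted over the list alone). For myeloid and dendritic cell markers, camera gave adjusted p = 0.000461 (higher), but they did not pass with an estimated correlation (adjusted p = 0.303) or with fry (adjusted p = 0.0869). The median of the myeloid markers was 0.62 ± 1.09 log2 CPM in Tr1 and -1.27 ± 1.58 in Teff cells.

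With culture as a block among the 9 cultured libraries, 3018 genes differed (1715 higher and 1303 lower), with T cell donor as a block 2185 did, and without a mean-variance trend in limma 1082. The count of 1801 was 1140 without Tr1 replicate 2 and 892 without the 3 cultured libraries with the most LYZ.

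The comparison with uncultured CD4+ T cells of the same T cell donors sets cultured Tr1 cells, sorted as memory CD4+ T cells, against uncultured total CD4+ T cells. Culture, subset and the restriction to memory cells are thus not separated, which bears on the naive and central memory genes below. LAG3 was 993-fold higher in Tr1 cells (12.69 ± 0.17 against 2.74 ± 0.44 log2 CPM, n = 3 and 2), ITGA2 32-fold (4.81 ± 0.47 against -0.20 ± 0.74 log2 CPM) and IL10 94.8-fold (6.88 ± 0.51 against 0.31 ± 0.71 log2 CPM). CXCR6, a chemokine receptor of tissue-homing effector cells, was 102-fold higher (adjusted p = 3.16e-09). RRM2, a subunit of ribonucleotide reductase that cells need to make DNA, was 44.8-fold higher. The named falls included genes of myeloid cells, such as IL1B (at least 171-fold) and FCN1 (at least 283-fold), and the median of the myeloid markers was 2.77 ± 0.20 log2 CPM in CD4 against 0.62 ± 1.09 in Tr1 cells.

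With limma, 7081 genes differed, 4222 higher and 2859 lower in Tr1 cells, and 3310 and 2222 of these by at least 2-fold. Besides LAG3, the named rises held CSF2 (5.10 ± 0.75 against -4.09 ± 1.39 log2 CPM), GDF10, a growth factor of the TGF-beta family (at least 156-fold), and the fatty acid transporter gene SLC27A2 (at least 151-fold). The noncoding genes LINC01480 (at least 193-fold) and RP11-305L7.3 (4.37 ± 0.39 against -3.44 ± 1.00 log2 CPM) rose too. FAIM2 and PAQR4 were at a count of 0 in both CD4 libraries and were at least 179.8-fold and 129-fold higher, taking 3 counts per library as the floor. Besides IL1B and FCN1, the named falls held LILRA2 (-4.43 ± 1.20 against 3.34 ± 0.22 log2 CPM), S100A8 (at least 91.2-fold), CSF3R (at least 106-fold) and PLD4 (at least 43.8-fold). MPEG1 and CTD-3214H19.16 were at a count of 0 in every Tr1 library and were at least 57.2-fold and 34.5-fold lower. The call of CTD-3214H19.16 ended, with an adjusted p of 0.0628 without CD4 replicate 2.

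Of 34 cell cycle genes measured, 31 were higher and 0 lower, and 32 and 0 adjusted over the list alone. TYMS (32.7-fold) and CDC20 (29.2-fold) were among the higher ones. As a list, cell cycle genes were higher (camera adjusted p = 5.48e-13, and adjusted p = 0.156 with an estimated correlation). Exhaustion-associated genes held 13 higher and 2 lower members of 17 measured, or 13 and 2 adjusted over the list alone. Exhaustion-associated genes had a camera adjusted p = 1.43e-07 as a list, higher, and adjusted p = 0.156 with an estimated correlation. Among co-stimulatory genes, 15 of 21 measured were higher and 2 lower (15 and 3 adjusted over the list alone). For co-stimulatory genes, camera gave adjusted p = 2.86e-06 (higher), and adjusted p = 0.156 with an estimated correlation. Of 18 co-inhibitory receptors measured, 11 were higher and 1 lower, and 11 and 1 adjusted over the list alone. CTLA4 (33.5-fold) and TIGIT (23.6-fold) rose. As a list, co-inhibitory receptors were higher (camera adjusted p = 0.000255, and adjusted p = 0.156 with an estimated correlation). Tr1-associated genes held 11 higher and 2 lower members of 18 measured, or 13 and 2 adjusted over the list alone. Tr1-associated genes had a camera adjusted p = 2.90e-05 as a list, higher, and adjusted p = 0.156 with an estimated correlation. Among cytotoxic granule genes, 10 of 16 measured were higher and 0 lower (10 and 1 adjusted over the list alone). PRF1, which encodes perforin (16.5-fold), and GZMA (26.2-fold) rose. For cytotoxic granule genes, camera gave adjusted p = 0.000138 (higher), and adjusted p = 0.156 with an estimated correlation. Of 19 naive and central memory genes measured, 3 were higher and 11 lower, and 3 and 12 adjusted over the list alone. CCR7 (12.5-fold) and KLF2 (3.62-fold), a factor of quiescent T cells, fell. As a list, naive and central memory genes were lower (camera adjusted p = 0.00275, and adjusted p = 0.215 with an estimated correlation). Immediate early genes held 2 higher and 12 lower members of 20 measured, or 3 and 13 adjusted over the list alone. FOS (4.33-fold), JUN (3.06-fold) and ATF3 (8.97-fold) fell. Immediate early genes had a camera adjusted p = 0.00109 as a list, lower, and adjusted p = 0.156 with an estimated correlation.

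Among glycolysis genes, 12 of 21 measured were higher and 1 lower (12 and 1 adjusted over the list alone). ENO1 was 6.89-fold higher. For glycolysis genes, camera gave adjusted p = 4.04e-05 (higher), and adjusted p = 0.156 with an estimated correlation. Of 30 oxidative phosphorylation genes measured, 16 were higher and 0 lower, and 18 and 0 adjusted over the list alone. NDUFB5 was 7.02-fold higher. As a list, oxidative phosphorylation genes were higher (camera adjusted p = 0.000326, and adjusted p = 0.304 with an estimated correlation). Cholesterol synthesis genes held 7 higher and 2 lower members of 22 measured, or 7 and 2 adjusted over the list alone. Cholesterol synthesis genes had a camera adjusted p = 0.0443 as a list, higher, and adjusted p = 0.156 with an estimated correlation. Among unfolded protein response genes, 9 of 22 measured were higher and 2 lower (12 and 2 adjusted over the list alone). CHAC1 (0.92 ± 1.11 against -3.98 ± 1.54 log2 CPM) and PDIA6 (6.08-fold) rose. For unfolded protein response genes, camera gave adjusted p = 0.00304 (higher), and adjusted p = 0.156 with an estimated correlation. Of 31 type I interferon genes measured, 18 were higher and 3 lower, and 19 and 5 adjusted over the list alone. ISG15 (5.40-fold) and OAS1 (9.97-fold) rose. As a list, type I interferon genes were higher (camera adjusted p = 0.000744, and adjusted p = 0.156 with an estimated correlation). MHC class II genes held 0 higher and 4 lower members of 13 measured, or 0 and 4 adjusted over the list alone. HLA-DRA was 6.88-fold lower. MHC class II genes had a camera adjusted p = 0.00258 as a list, lower, and adjusted p = 0.166 with an estimated correlation. Among myeloid and dendritic cell markers, 1 of 28 measured were higher and 13 lower (1 and 14 adjusted over the list alone). Myeloid and dendritic cells express MHC class II. For myeloid and dendritic cell markers, camera gave adjusted p = 0.000849 (lower), and adjusted p = 0.304 with an estimated correlation.

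With T cell donor as a block the count of 7081 was 7343, and no library left out or other setting tried moved it by more than 1.5 times. The CD4 group has only 2 libraries, 1 per donor.

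DN and Teff cells carried neither sort marker and came from the T-allo10 and the T-allo culture, so this comparison asks how cells of 1 sorted phenotype differ by the kind of culture. HLA-DRA, an MHC class II chain that presents peptides, was 6.94-fold lower in DN cells (3.71 ± 0.65 against 6.50 ± 0.34 log2 CPM, n = 3 each, adjusted p = 0.000905), and HLA-DMA 2.65-fold lower. ENTPD1 was 10.9-fold lower in DN cells (2.43 ± 0.31 against 5.88 ± 0.29 log2 CPM), IFNG 3.73-fold and CXCR6 3.55-fold lower. LRRC32 was 11.2-fold higher and AREG, a growth factor gene, 5.85-fold higher in DN cells. The sort marker LAG3 was at 7.30 ± 0.75 in DN and 7.22 ± 0.55 log2 CPM in Teff cells (adjusted p = 0.940), and ITGA2 at 0.71 ± 0.79 and 2.38 ± 0.80 (adjusted p = 0.124). With culture as a block, ITGA2 was lower in DN cells (adjusted p = 0.00674), with log2 differences of -1.50, -1.50 and -1.99 in cultures 1, 2 and 3, and LAG3 did not pass (adjusted p = 0.867).

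With limma, 413 genes differed, 163 higher and 250 lower in DN cells, and 139 and 180 of these by at least 2-fold. Among the named rises, MAP7, a microtubule-binding protein (at least 19.7-fold), WNT10A, a secreted signalling protein (7.81-fold), and IFI44L, an interferon-induced gene (7.61-fold), kept the call with any 1 library left out. Besides ENTPD1, the named falls that did so were CYP1B1 (31.6-fold), CD79A, known from the B cell receptor (28.5-fold), and ASB2 (15.9-fold). LRRN3 (15.8-fold), BEND5 (14.0-fold) and the transcription factor gene SOX4 (10.6-fold) fell too.

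The other named rises and falls lost the call with some library of DN or Teff cells left out. The adjusted p of SEMA5A was 0.111 without DN replicate 2, 0.132 without DN replicate 3, 0.105 without Teff replicate 1 and 0.116 without Teff replicate 2. For ANKRD18A it was 0.0696 without DN replicate 2, 0.0556 without DN replicate 3 and 0.0589 without Teff replicate 2. For FLJ21408 it was 0.0696 without DN replicate 2, 0.112 without DN replicate 3, 0.0822 without Teff replicate 1 and 0.0754 without Teff replicate 2. For CRIP2 it was 0.0836 without DN replicate 1, 0.134 without DN replicate 2, 0.0784 without Teff replicate 1, 0.0572 without Teff replicate 2 and 0.0980 without Teff replicate 3. For KRT1 it was 0.0734 without DN replicate 3, 0.0603 without Teff replicate 1 and 0.0590 without Teff replicate 2. For ARNTL2, a fall, it was 0.0546 without DN replicate 1, 0.109 without DN replicate 3, 0.0869 without Teff replicate 1, 0.0793 without Teff replicate 2 and 0.0660 without Teff replicate 3. IL10 was at least 7.26-fold higher in DN cells (1.58 ± 1.26 against -1.35 ± 0.99 log2 CPM, adjusted p = 0.0325). This call ended with an adjusted p of 0.0768 without DN replicate 1, 0.141 without DN replicate 3, 0.0570 without Teff replicate 1, 0.107 without Teff replicate 2 and 0.0506 without Teff replicate 3, and of 0.0595 under quantile normalization.

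Of 13 MHC class II genes measured, 0 were higher and 9 lower, and 0 and 11 adjusted over the list alone. As a list, MHC class II genes were lower (camera adjusted p = 1.04e-14, and adjusted p = 0.0467 with an estimated correlation). Cell cycle genes held 0 higher and 5 lower members of 34 measured, or 0 and 27 adjusted over the list alone. MCM4, a part of the replicative helicase, was 2.40-fold lower. Cell cycle genes had a camera adjusted p = 9.35e-20 as a list, lower, and adjusted p = 0.227 with an estimated correlation. Among type I interferon genes, 4 of 31 measured were higher and 0 lower (12 and 1 adjusted over the list alone). MX1 was 2.11-fold higher. For type I interferon genes, camera gave adjusted p = 1.26e-06 (higher), and adjusted p = 0.119 with an estimated correlation. Of 19 naive and central memory genes measured, 3 were higher and 0 lower, and 8 and 0 adjusted over the list alone. MAL (4.03-fold) and KLF3 (3.48-fold) rose. As a list, naive and central memory genes passed with camera as higher (adjusted p = 7.22e-06), but not with an estimated correlation (adjusted p = 0.227) or with fry (adjusted p = 0.0760). Immediate early genes held 4 higher and 0 lower members of 20 measured, or 6 and 3 adjusted over the list alone. NR4A2 (3.72-fold) and JUNB (2.49-fold) rose. Immediate early genes had a camera adjusted p = 0.0415 as a list, higher, but did not pass with an estimated correlation (adjusted p = 0.565) or with fry (adjusted p = 0.205). Among exhaustion-associated genes, 1 of 17 measured were higher and 5 lower (3 and 8 adjusted over the list alone). For exhaustion-associated genes, camera gave adjusted p = 0.00377 (lower), and adjusted p = 0.382 with an estimated correlation. Of 18 Tr1-associated genes measured, 2 were higher and 3 lower, and 4 and 7 adjusted over the list alone. IRF4 was 3.43-fold lower. As a list, Tr1-associated genes passed with camera as lower (adjusted p = 0.0214), but not with an estimated correlation (adjusted p = 0.467) or with fry (adjusted p = 0.0517). Chemokine and homing receptors held 1 higher and 5 lower members of 22 measured, or 6 and 7 adjusted over the list alone. CXCR3 was 2.71-fold lower. As a list, chemokine and homing receptors did not pass with camera (adjusted p = 0.50). Among cytokines, 2 of 21 measured were higher and 2 lower (3 and 4 adjusted over the list alone). Cytokines did not pass as a list with camera (adjusted p = 0.196). Of 30 oxidative phosphorylation genes measured, 0 were higher and 1 lower, and 0 and 4 adjusted over the list alone. As a list, oxidative phosphorylation genes passed with camera as lower (adjusted p = 2.81e-07), but not with an estimated correlation (adjusted p = 0.467) or with fry (adjusted p = 0.0603).

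With culture as a block among the 9 cultured libraries, 1256 genes differed (451 higher and 805 lower), with T cell donor as a block 671 (265 and 406), without a mean-variance trend 88, and with the libraries of DN and Teff alone 200. The count of 413 was 152 without DN replicate 2, 117 without DN replicate 3, 144, 162 and 227 without Teff replicate 1, 2 and 3, and 85 without the 3 cultured libraries with the most LYZ, where 44 were higher and 41 lower.

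Genes that set Tr1 cells apart from every other group were counted from the contrasts with DN, Teff and CD4 cells. A total of 1023 genes passed the test in the same direction in all 3, 616 higher and 407 lower in Tr1 cells. LAG3, ITGA2, IL10, CSF2, CTLA4, PDCD1, GZMA, NKG7, PRDM1 and CD8A were among those higher, and CCR7, TCF7, LEF1 and ADAM23 among those lower. Lists drawn independently of each other would share 23.0 higher and 8.27 lower genes in all 3. Simulated unchanged groups give no value for chance here, since simulations of each contrast alone already called 0 genes. The 3 contrasts share the 3 Tr1 libraries, which cannot be split further, so part of the excess over independent lists can come from that. The count was 1227 (731 higher and 496 lower) with T cell donor as a block, 625 without a mean-variance trend and 452 without the 3 cultured libraries with the most LYZ, and under quantile normalization 442 were higher and 447 lower.

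**Figure D3:**
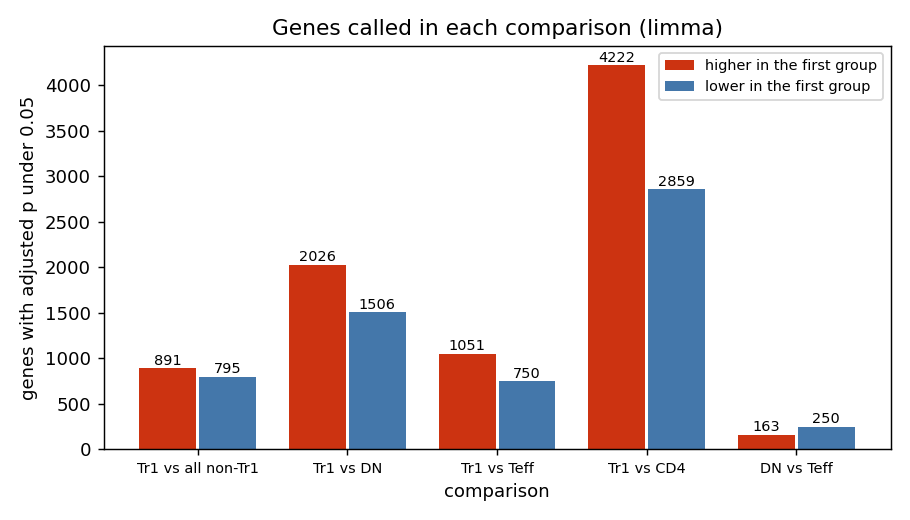
Number of genes with an adjusted p under 0.05 (vertical axis, limma) in each of the 5 comparisons (horizontal axis), with red bars for genes higher and blue bars for genes lower in the group named first. The counts run from 163 higher and 250 lower in DN against Teff to 4222 higher and 2859 lower in Tr1 against CD4.

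**Figure D4:**
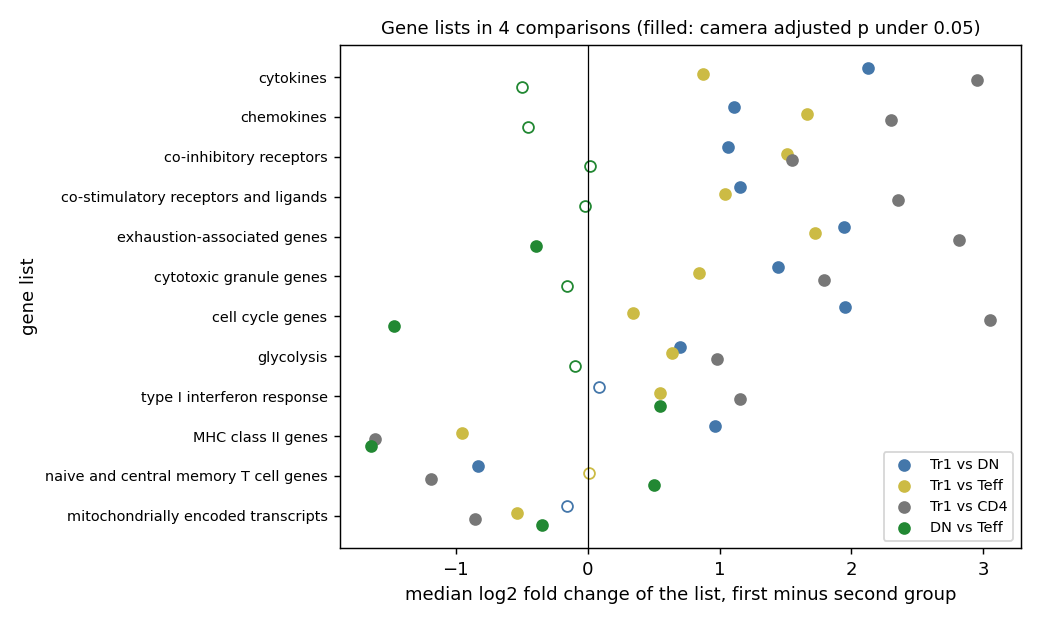
Median log2 fold change (horizontal axis, first minus second group) of the members of 12 gene lists (vertical axis) in 4 comparisons, 1 colour each, where filled points have a camera adjusted p under 0.05. The cell cycle list lies at 1.96 for Tr1 against DN, at 0.34 for Tr1 against Teff and at -1.47 for DN against Teff.

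Some lists serve as checks of cell type or RNA quality. CD4 was 8.19-fold higher in Tr1 than in DN cells, 7.47-fold than in Teff and 26.5-fold than in CD4 cells, values that reads running on from its neighbour LAG3 may make up in part or whole. In Tr1 against DN cells, 10 of 14 CD4 T cell identity genes were higher and 1 lower (11 and 1 adjusted over the list alone). As a list, CD4 T cell identity genes were higher (camera adjusted p = 3.68e-08, and adjusted p = 0.151 with an estimated correlation). The CD8 and gamma-delta T cell markers had group medians of 3.28 ± 0.26 log2 CPM in Tr1, 2.40 ± 0.44 in DN, 2.47 ± 0.27 in Teff and 1.38 ± 0.21 in CD4. Their camera adjusted p for Tr1 was 0.0113 against all others, 0.163 against DN, 0.0868 against Teff and 0.0205 against CD4, the first and last with adjusted p = 0.265 and 0.156 with an estimated correlation, and with fry it was 0.0464 against DN and 0.0430 against Teff, both higher. B cell markers had a camera adjusted p for Tr1 of 0.972 against DN, 0.308 against Teff and 0.749 against CD4, but with fry they were lower than in Teff cells in Tr1 (adjusted p = 0.0169) and in DN (adjusted p = 0.0261). In DN against Teff, 0 of 7 B cell markers measured were higher and 1 lower, and camera gave adjusted p = 0.475. The median log2 difference there was 0.27, opposite in sign to the fry direction. The medians of the B cell markers were -0.82 ± 1.52 log2 CPM in Tr1, 0.36 ± 0.55 in DN, 0.40 ± 1.30 in Teff and 1.34 ± 0.25 in CD4. Natural killer cell markers had 0.206 against DN, 0.216 against Teff and 0.828 against CD4, with 0.0464 by fry against DN (higher), and platelet and erythroid markers 0.972 against DN, 0.988 against Teff and 0.658 against CD4.

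Mitochondrially encoded transcripts had a median of 10.43 ± 0.26 log2 CPM in CD4, 9.53 ± 0.33 in DN, 9.70 ± 0.32 in Teff and 9.19 ± 0.33 in Tr1. In Tr1 against CD4 cells, 0 of 13 were higher and 10 lower (1 and 12 adjusted over the list alone). As a list, mitochondrially encoded transcripts were lower (camera adjusted p = 0.000383, and adjusted p = 0.319 with an estimated correlation). In Tr1 against Teff they passed with camera as lower (adjusted p = 0.000376, with 2 members lower). They did not pass there with an estimated correlation (adjusted p = 0.373) or with fry (adjusted p = 0.145). The same held in Tr1 against all others (camera adjusted p = 0.00344, 0.421 with an estimated correlation and 0.129 with fry). It also held in DN against Teff (camera adjusted p = 0.0175, 0.641 with an estimated correlation and 0.467 with fry). In Tr1 against DN the camera adjusted p was 0.228. The heat shock list had a median of 7.62 ± 0.23 in CD4 and of 9.69 ± 0.19, 9.62 ± 0.43 and 9.80 ± 0.06 in DN, Teff and Tr1. In Tr1 against CD4 cells, 9 of 12 heat shock genes were higher and 0 lower (9 and 0 adjusted over the list alone). As a list, heat shock genes were higher (camera adjusted p = 1.18e-05, and adjusted p = 0.156 with an estimated correlation). Heat shock genes had a camera adjusted p of 0.972 against DN, 0.356 against Teff, 0.100 against all others and 0.421 in DN against Teff. The list of sort markers, ITGA2 and LAG3, had a camera adjusted p of 0.000164 against DN cells, and adjusted p = 0.127 with an estimated correlation. In Tr1 against DN cells, 5 of 19 helper lineage factors were higher and 3 lower (5 and 3 adjusted over the list alone). As a list, helper lineage factors were higher (camera adjusted p = 0.00649, and adjusted p = 0.157 with an estimated correlation).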

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

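Chosen after the data were seen were the fits with voom weights, the fits without the 3 cultured libraries with the most LYZ (Tr1 replicate 1, DN replicate 3 and Teff replicate 3), and for the genes shared by the 3 contrasts also quantile normalization, the upper part of expression, limma without a trend and the mean of cultures. Without those 3 libraries, DN and Teff come from T cell donor 1 alone while Tr1 keeps both donors. These fits are thus unbalanced for donor in the Tr1 comparisons. Alternatives that need counts were not run. In the 5 comparisons, no gene called both as reported and in an alternative had opposite directions in the 2, and no named gene or list reversed in the settings counted here. Culture as a block ended no call of a named gene or list, and 8, 20 and 44 named genes not called in Tr1 against DN, Tr1 against Teff and DN against Teff passed with it. Of 567 called results for named genes, 528 kept the call under quantile normalization, 564 with T cell donor as a block and 409 in every run that left out 1 library. Of 273 results not called, 19, 28 and 39 passed in those settings. Quantile normalization lowered the share of higher genes among those called in Tr1 against DN from 57.4% to 48.7%. In Tr1 against all others that share was 52.8%, and 45.6% under quantile normalization, 47.1% without the trend, 48.2% without Tr1 replicate 3 and 71.6% with voom weights, where 1550 genes were called. In DN against Teff it was 39.5%, and 51.8% without the LYZ libraries. Where a count moved by more than 1.5 times, the cause was not tested, except that fewer libraries leave less power by construction.

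Tr1 against all others gave 1686 genes, and 301 with the mean of both cultures of T cell donor 1 and a donor block, 5147 in the 4-group fit against the mean of the group means, 300 without the LYZ libraries, and 649 to 1912 with 1 library left out (649, 685 and 731 without Tr1 replicate 1, 2 and 3). Tr1 against DN gave 3532, and 1511 without the LYZ libraries and 2349 (without DN replicate 3) to 3374 with 1 library left out. Tr1 against Teff gave 1801, and 1082 without the trend, 3018 with culture as a block, 892 without the LYZ libraries and 1140 (without Tr1 replicate 2) to 1365 with 1 library left out. Tr1 against CD4 gave 7081, and 4922 to 6736 with 1 library left out. Leaving out a CD4 library leaves a lone library that is assumed to vary like the other groups. DN against Teff gave 413, and 88 without the trend, 671 with T cell donor as a block, 1256 with culture as a block, 200 with the DN and Teff libraries alone, 85 without the LYZ libraries and 117 to 442 with 1 library left out (152 and 117 without DN replicate 2 and 3, and 144, 162 and 227 without Teff replicate 1, 2 and 3). Genes shared by the 3 Tr1 contrasts numbered 1023, and 625 without the trend, 452 without the LYZ libraries and 722 to 1084 with 1 library left out. Of 145 list tests, 89 passed, 13 with an estimated correlation, 86 with fry and 89 with T cell donor as a block. The 13 were co-stimulatory, Tr1-associated, cytotoxic granule and exhaustion-associated genes in Tr1 against all others, DN and Teff, and MHC class II genes in DN against Teff. With fry, 75 of the 89 kept the call, 14 lost it and 11 other tests passed. The 14 included cell cycle genes and mitochondrially encoded transcripts in Tr1 against all others and Teff, and myeloid markers in Tr1 against Teff. In DN against Teff they included Tr1-associated, naive and central memory, immediate early and oxidative phosphorylation genes and mitochondrially encoded transcripts. Depth limits genes near the floor at a count of 0, whose folds are bounds.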

Other observations

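Tests chosen after the result was seen, or whose bound was worded after it, were those of the lysosomal rise as a group, of carried-over myeloid RNA, of reads running on from LAG3, of neighbouring genes, of myeloid cells in the CD4 libraries, and of the splits for Tr1 against all others, and the lysosomal list was written then too. Lysosomal genes, which encode the enzymes and membrane proteins of the degradative compartment, were higher in Tr1 cells, and 1 of the list, LAMP1, is also among the cytotoxic granule genes. Of 53 measured, 32 were higher and 0 lower than in DN cells, 21 and 0 than in Teff cells and 33 and 2 than in CD4 cells, and 19 were higher than in each of the 3. Against DN cells, the protease genes LGMN (9.95 ± 0.55 against 5.70 ± 0.21 log2 CPM, n = 3 each, adjusted p = 1.03e-06 by limma), CTSC, CTSB and CTSD were 19.1-fold, 4.87-fold, 3.29-fold and 3.39-fold higher, and GRN, which encodes progranulin, was 4.0-fold higher, all chosen after their values were seen. DN against Teff cells gave 0 higher and 3 lower members, with a median log2 difference of -0.26 over the list. Camera with an estimated correlation gave p = 0.0124 (lower) there, so differences in this list were not confined to Tr1 cells.

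For this lysosomal rise, camera with an estimated correlation gave p = 0.000585 against Teff cells, 0.000350 against DN cells and 0.0122 against all others, which restates the rise, as the list was written after it was seen. The scaling of the libraries is argued against, since 84.4% of the lysosomal genes called higher than in DN cells kept the call under quantile normalization. After the sort, 10 abundant myeloid markers still summed to 110.4, 16.6 and 15.6 CPM in Tr1 replicates 1, 2 and 3. The summed lysosomal excess over DN cells was 6169, 4760 and 6048 CPM, so the markers reached at most 1.79% of it. In culture 3 the markers summed to less in Tr1 (15.6 CPM) than in DN cells (64.2 CPM). These values argue against RNA of dendritic cells or monocytes as the main source, but only for cells rich in these markers. A lysosomal programme of the Tr1 cells stays a hypothesis from the same data, and activation by the culture and the sort were not tested. Donors are balanced over DN, Teff and Tr1, since each pair of T cell and dendritic cell donors gave 1 library of each. CD86, CD68, C1QB, MS4A6A, CCL18, MERTK, HMOX1 and LYN, which myeloid cells also express, are not covered by this. CCL18 was at 4.37, 2.34 and 0.96 and CD68 at 3.89, 2.74 and 1.87 log2 CPM in Tr1 replicates 1, 2 and 3. MERTK was at 4.44, 4.01 and 4.76 there and at 0.20, -0.35 and -0.19 in DN replicates 1, 2 and 3. The ratio of the 10 markers to lysosomal RNA in the cultured dendritic cells was not measured.

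PTMS, LAG3 and CD4 lie next to each other on a chromosome and were all higher in Tr1 cells. Of 13309 genes placed in order, 539 were higher in Tr1 than in each other group, and 32 adjacent pairs of these compare with a mean of 21.2 and a highest value of 44 in 10000 shuffles (one-sided permutation p = 0.0144), leaving out pairs with the same first 3 letters of the symbol, 4 other related pairs and the 2 pairs of LAG3 that prompted the test. The excess of CD4 over DN cells of the same culture was 52.6% to 55.5% of that of LAG3. For PTMS it was 1.76% to 2.08%. LAG3 lies between PTMS and CD4, so transcripts running past its end can reach either gene but not both. For the gene they can reach, reads running from LAG3 and a rise of the gene itself cannot be told apart. The libraries keep no strand and the table no positions of reads. A shared regulation of the region may add to this and was not tested.

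Myeloid markers were higher in the CD4 libraries than in the cultured groups. The list's median log2 difference from CD4 was -2.73 in Tr1, -3.70 in DN and -3.63 in Teff cells, each at percentile 0 of 10000 random lists of like expression, though random lists ignore the correlation between genes. In Tr1 against CD4 cells 1 of 28 members was higher, 13 were lower and 14 were not called, and the list's call is lost with an estimated correlation (adjusted p = 0.304), so myeloid cells among the uncultured cells are a candidate source only. The 10 abundant markers summed to 693 and 1034 CPM in the CD4 libraries. Loss of such transcripts from T cells during culture was not tested and stays open, as does the purity of the isolation, which the labels do not give.

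Other splits of the libraries were counted for the gene calls. For Tr1 against all others, 100 splits were counted, the real one and a random draw from the others. Of these, 3, the real one included, gave 1686 genes or more. This share under 0.05 would exclude a chance split if libraries were exchangeable, which libraries that share a culture or donor are not. The highest other split gave 3448 genes and set CD4 replicates 1 and 2 with DN replicate 3 against the rest, and another gave 2359 with DN replicate 2 in its place, which points to a structure of the samples. Both CD4 libraries with Teff replicate 3 gave 1 gene and with Teff replicate 1, Tr1 replicate 1 or Tr1 replicate 2 gave 0. On principal component 1, DN replicates 3 and 2 lay at -21.4 and -12.1, nearer the CD4 libraries than Teff replicate 3 at 11.5. A distant library joined to the CD4 libraries widens the spread within their group. The low counts therefore cannot show whether the distance of the CD4 libraries gives the high ones. For Tr1 against DN, Tr1 against Teff and DN against Teff, 1 of 10 splits, the real one, reached the counts of 3532, 1801 and 413, the highest other split gave 0 genes, and 10 splits are too few for a share under 0.05. In each of the 3, the 4 splits that part all 3 culture pairs, as the real one does, also gave a highest other count of 0. Splits that mix 2 differing groups widen the spread within each side, so these counts of 0 cannot tell what chance would give.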
